A study of Arabidopsis thaliana with 5 samples.

How the data were processed

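Gene expression was measured in cotyledons of 7-day-old Arabidopsis thaliana seedlings of the wild type Col-0 and of a mutant line labelled ckg. Cotyledons are the seed leaves, the embryonic leaves of the seedling. Per the labels, seedlings were grown in long days, total RNA was extracted with TRIzol, and the samples were 2 biological replicates of Col-0 and 3 of ckg. Each RNA was labelled with the dye Cy3 and hybridised alone to an Agilent array (1 colour), so each sample is 1 array. Groups and replicate numbers were taken from the labels. A label field of the mutant samples writes "cgr" where the titles write ckg; the line was taken, from outside knowledge, to carry a mutation in CYTOKININ-RESPONSIVE GROWTH REGULATOR (AT5G50915), a basic helix-loop-helix transcription factor.

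Per the file headers, the authors' scanner images were read with Agilent Feature Extraction 10.7.1.1, and the values used here are spot intensities: a processed intensity that the software had background-subtracted, spatially detrended and, for dim spots, replaced by a small positive value, with no scaling between arrays. The raw median intensity of each spot and of its local background, per the file headers not normalised, served 1 alternative. Other columns deposited in the scanner files are flags of 0 or 1 per spot for signal well above background, outlier spots and saturation. No spot was saturated (0 on each array). The authors' deposited series table holds log2 values whose scale and normalisation no header states. Within each array their ranks equalled those of the raw median intensity (Spearman correlation 1 on each of the 5 arrays), and the median was 8.41 on each array, as after quantile normalisation of log2 median intensities without background subtraction. These log2 values are levels, not ratios, and were not centred per gene. They served as an alternative.

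For the results, log2 of the processed intensity minus the array's own 75th percentile over non-control spots was used. Control spots and outlier spots were left out (35 to 197 non-control spots per array), and spots of a probe were averaged. Probe accessions were matched, without versions, to locus tags through the TAIR10.1 gene table: 34358 of 43603 non-control probes matched, and 9245 did not. The table was used for names and for the order of neighbouring genes. No coordinates are given, because the build behind the array design is not given in the sources used here. A gene with several probes (6940 of 25433 genes) was represented by its probe with the highest mean signal. Among list members, 180 of 244 other probes had the same sign of difference as the probe used, 64 had the opposite sign and 11 lay over 1 log2 unit away. A gene was tested where its probe was well above background on every array of at least 1 group, which held for 18123 genes.

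The comparison, ckg minus Col-0 over all 5 arrays, was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given with log2 differences are limma standard errors (SE). With 3 residual degrees of freedom, the number of arrays limits the precision. Groups of 2 and 3 make 10 splits, so an exact permutation test of a single value cannot give a p below 0.1. Per-array list means are means of members after centring each gene on its mean over the arrays.

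Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, over members with a value on every array, and again with the correlation estimated for each list. They were also tested with fry, which asks whether genes of a list move on balance one way (or, in its mixed form, either way) and does not compare the list with other genes. P-values were adjusted over the 34 lists. Counts of members past 0.05 are given over all genes and adjusted over the list alone. A gene not well above background on any array of a group has only a bound there. Its fold is the brighter group's mean over the mean, per array of the dim group, of the higher of the gene's own signal and the lowest signal well above background, written as "at least".

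The groups, the test, the filter, the 34 lists, the named-genes rule and the alternatives were set before the data were examined, except where said. The rule named the gene taken as mutated, the 12 largest rises and 12 largest falls past the threshold, up to 3 genes per direction that passed the test and were measured in 1 group alone, the 2 members of each list with the smallest adjusted p (4 where members pass), WEE1 and the type-A response regulators. As no gene passed the threshold, its parts on the largest changes and on genes measured in 1 group alone named no gene. Alternatives changed the background correction, scaling, filter, outlier spots, choice of probe, variance model, replicate numbers as a block, threshold and set test, used the authors' series table, or left out each array. Where the values or the arrays changed, the filter and the choice of probe were applied anew, so measured members of a list could differ. The mean spot intensity that the normexp alternative called for is not used here, and the median intensity with an offset of 50 took its place. That change, a threshold of 0.10 and the test of unmatched probes were chosen after seeing the data.

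The fit and the list tests were tested on simulated data: 10 sets of 5 arrays over 17898 genes, with each gene's own mean and residual spread, 200 genes changed and the DNA replication list shifted by -0.5. At the threshold, limma called 0.896% of genes changed 1.5-fold, 33.9% of those changed 2-fold and 73.9% of those changed 4-fold, with 48 calls of unchanged genes in all. The shifted list was called in 10 of 10 sets with the preset correlation and in 0 with an estimated one, and 3 calls of unshifted lists were made in all. Noise was drawn independently for each gene. Estimated correlations in the data were 0.25 for the replication list, 0.21 for G2 and M phase genes and 0.94 for heat shock genes. The few false list calls at the preset correlation therefore do not carry over to the data. A list not called with an estimated correlation is not shown to be unshifted. The shares of single genes called do not carry over to the data either. In the data 0 genes passed, and AT5G50915, at least 29.6-fold lower in ckg, was not called. A count of 0 therefore does not show that few genes changed 4-fold or more. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. A result on a withheld gene was left out.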

Results

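The comparison between ckg and Col-0 cotyledons asks which transcripts differ when the growth regulator gene named by the line is mutated. The arrays carried 43803 non-control spots. On both Col-0 arrays and on ckg replicates 1 and 2, between 66.7% and 70.0% of spots were well above background; on ckg replicate 3 the share was 52.4% (22955 spots). Its lowest processed signal was 31.0, against 2.68 to 4.01 on the other arrays, so weakly expressed genes were measured least well on that array. Over the tested genes, the Col-0 arrays correlated at r = 0.992 with each other, the ckg arrays at 0.979 to 0.989, and arrays of different genotype at 0.977 to 0.986 (Pearson r across genes, which are not independent replicates). Both Col-0 arrays lay on slide 1 (scan 1) and all ckg arrays on slide 2 (scan 2), so slide and genotype cannot be told apart in any comparison.

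The gene taken as mutated, AT5G50915 on chromosome 5, gave a clear signal in Col-0 and none above background in ckg. Scaled log2 signal of the probe used was -1.19 ± 0.06 (SD, n = 2) in Col-0 and -7.11 ± 1.58 (SD, n = 3) in ckg, and processed signals were 1070 and 962 in Col-0 against 6.46, 16.5 and 51.3 in ckg. The probe was well above background on 2 of 2 Col-0 arrays and 0 of 3 ckg arrays, so the transcript was at least 29.6-fold lower in ckg. The other probes of the gene gave bounds of at least 29.7-fold and 18.7-fold lower. The limma adjusted p was 0.103 for a fitted log2 difference of -5.91 ± 0.89 (SE), which rests on ckg signals near the floor. With the authors' deposited log2 values the difference was -3.63 and the limma adjusted p 0.0437. The position of the lesion relative to the probes is not given in the sources used here.

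**Figure D1:**
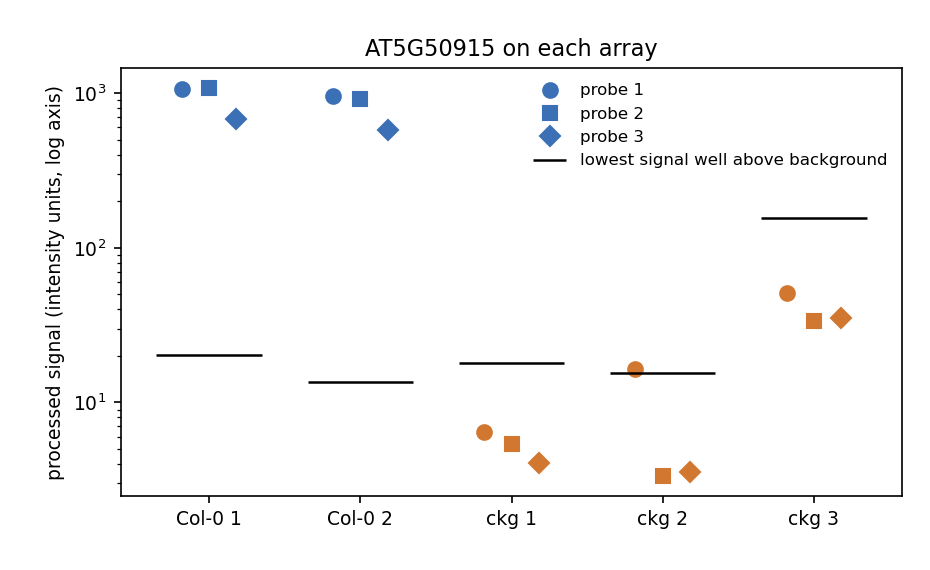
Processed signal (intensity units, log axis) of the 3 probes of AT5G50915 on each array, with Col-0 in blue and ckg in orange; black bars mark the lowest signal called well above background on that array. All probes gave 576 to 1082 in Col-0 and 3.32 to 51.3 in ckg; probe 1 on ckg replicate 2 (16.5) lay at the height of the bar (15.4) but was not itself called well above background.

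Genes of DNA replication were lower in ckg as a group, and genes of the G2 and M phases were lower to a smaller extent. Of 21 measured replication genes, 20 had lower signal in ckg and the list mean fell by 1.09 (log2, SD over members 0.42), a mean 2.12-fold lower level (camera adjusted p = 2.5e-14). The adjusted p was 0.625 with an estimated correlation. PCNA1, a sliding clamp of the replication fork, was lower by 1.48 ± 0.17 (SE) and FAS2, a subunit of chromatin assembly factor 1, by 1.04 ± 0.13. The 6 subunits of the MCM helicase, named after their values were seen, had log2 differences of -1.38 to -0.996. RNR2A, a small subunit of ribonucleotide reductase, was the exception at 0.20 ± 0.14. Over all genes tested 0 replication genes passed limma's adjusted p of 0.05, and 18 were at an unadjusted p under 0.05. Adjusted over the list alone 18 passed, all lower, with 18 to 19 when 1 ckg array was left out and 16 with quantile scaling. The list mean was -0.998 without Col-0 replicate 1 and -1.17 without Col-0 replicate 2. The filter on all 5 arrays kept only 11 of the 21 genes, and 9 of these 11 passed over the list alone. In 19 of the 21 every ckg array lay below every Col-0 array. Mean levels of the list were 0.74 and 0.56 on the Col-0 arrays and -0.60, -0.25 and -0.46 on the ckg arrays (exact permutation p = 0.1, the smallest these groups allow). The fry adjusted p was 0.0766 in a single direction and 0.00685 in its mixed form.

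Of 27 measured G2 and M phase genes, 25 had lower signal in ckg and the list mean fell by 0.39 (log2, SD 0.34; camera adjusted p = 1.8e-05). The adjusted p was 0.986 with an estimated correlation, and the fry adjusted p was 0.198. Examples were the A-type cyclin CYCA2;3 (-0.82 ± 0.11) and the B-type cyclin CYCB2;2 (-0.58 ± 0.12). CYCB1;1 (0.03 ± 0.36), which marks cells entering mitosis, lay near 0, below 0 with quantile scaling. Of 4 other probes of these genes, 2 had the opposite sign, 1 of CDKB1;2 (0.69, against -0.33) and 1 of KN (0.42, against -0.22). The filter on all 5 arrays kept only 13 of the 27 genes. Adjusted over the list alone, 1 gene (CYCA2;3) passed, 13 were at an unadjusted p under 0.05, and 0 passed over all genes in limma. The 1 over the list alone became 7 with normexp, 8 with scaling by the median, 10 without ckg replicate 2, and 0 without either Col-0 array or ckg replicate 1. On 3 of 3 ckg arrays the list mean lay below both Col-0 arrays (exact permutation p = 0.1). The 15 measured G1/S regulators did not pass (mean -0.14, camera adjusted p = 0.779), with CYCD4;1 at -0.87 ± 0.16 and DEL1, an atypical E2F factor, at -1.32 ± 0.43. Among 16 genes of CDK inhibition and endoreduplication (mean -0.12, camera adjusted p = 0.763), WEE1, a kinase that inhibits cyclin-dependent kinases, was at -1.18 ± 0.22 and FZR2, an activator of the anaphase-promoting complex, at -0.68 ± 0.14; both passed adjusted over the list alone, and neither over all genes.

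**Figure D2:**
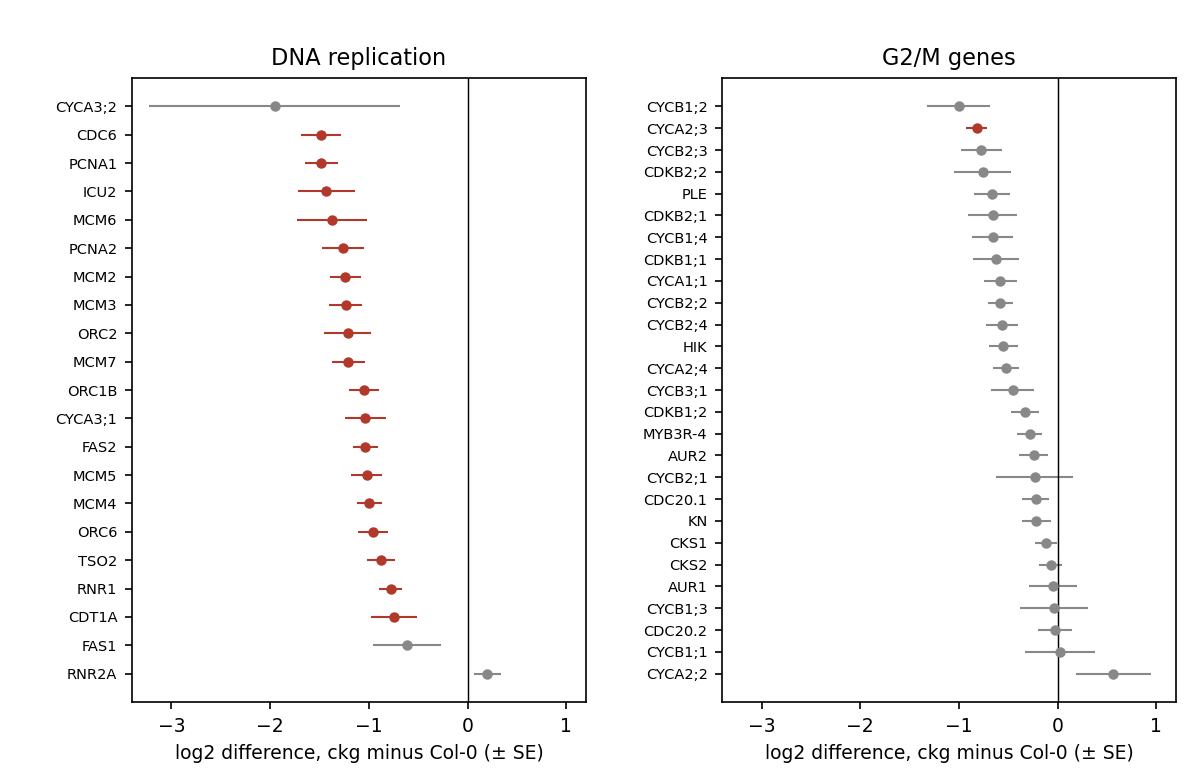
Log2 difference in signal (ckg minus Col-0, x axis) for each measured member of the DNA replication list (left) and the list of G2 and M phase genes (right); points are limma estimates over 5 arrays, bars are ± 1 SE, and red points have an adjusted p under 0.05 over the list alone. Of the replication genes 20 of 21 lie below 0 and 18 are red; of the G2 and M phase genes 25 of 27 lie below 0 and 1 is red.

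Expansins, proteins that loosen cell walls, were lower in ckg, with 14 of 16 measured members below Col-0 and a list mean that fell by 0.49 (log2, SD 0.40; camera adjusted p = 1.6e-04). The adjusted p was 0.625 with an estimated correlation, and the fry adjusted p was 0.0789. EXPB1 was lower by 1.34 ± 0.26 (SE) and EXPA13 by 0.54 ± 0.11. Over all genes 0 expansins passed in limma, 7 were at an unadjusted p under 0.05, and 5 passed adjusted over the list alone, a count of 0 without either Col-0 array, 1 without ckg replicate 2 and 8 without ckg replicate 3. On 3 of 3 ckg arrays the list mean lay below both Col-0 arrays (exact permutation p = 0.1). Without the filter on dim probes, which adds expansins near background, the list mean was -0.03 and camera still called it (adjusted p = 0.00348). Other wall genes did not pass: the primary-wall cellulose synthases had a mean of -0.24 over 6 genes (camera adjusted p = 0.191; CESA1 -0.29 ± 0.12, CESA3 -0.23 ± 0.10). The 20 xyloglucan endotransglucosylase/hydrolases had a mean of 0.02, which turned negative under other scalings (camera adjusted p = 0.916; XTH32 -0.77 ± 0.16, XTH31 -0.96 ± 0.21).

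Hormone lists did not pass camera, or fry in a single direction; in its mixed form fry called the lists of type-A response regulators (adjusted p = 0.00594), cytokinin metabolism (0.00257), brassinosteroid (0.00594) and gibberellin (0.00748). Among the type-A response regulators, which are induced by cytokinin and damp its signalling, ARR17 (1.11 ± 0.17) and ARR16 (0.92 ± 0.16) were higher and ARR8 (-0.75 ± 0.14) lower, and these 3 of 9 measured members passed adjusted over the list alone, with 0 over all genes. The other members differed by less than their errors: ARR5 (-0.24 ± 0.28), ARR7 (-0.41 ± 0.52, above 0 with normexp and with the series table), ARR9 (0.14 ± 0.22), ARR15 (-0.46 ± 0.76), ARR4 (-0.10 ± 0.22) and ARR6 (-0.09 ± 0.49). The list mean was 0.01 and its median -0.10 (camera adjusted p = 0.916), and the mean ran from -0.25 to 0.27 when 1 array was left out. Cytokinin metabolism genes had a mean of 0.07 over 11 genes (camera adjusted p = 0.779; IPT2 -0.38 ± 0.10, LOG1 0.92 ± 0.31), and cytokinin perception and transduction genes a mean of -0.02 over 17 (camera adjusted p = 0.925; RR10 -0.27 ± 0.14, AHP2 -0.23 ± 0.13). In the brassinosteroid list (mean -0.20 over 15 genes, camera adjusted p = 0.450), PRE1, a small helix-loop-helix growth regulator, was at -1.07 ± 0.16 and passed over the list alone, and BES1 was at 0.40 ± 0.12. Auxin-responsive genes had a mean of -0.002 over 15 genes (camera adjusted p = 0.944), which turned positive under other scalings. IAA29 was at -0.71 ± 0.13 and IAA17 at -0.76 ± 0.14, though another probe of IAA17 gave 0.04. Gibberellin genes had a mean of -0.07 over 21 genes, positive under another scaling (camera adjusted p = 0.987; GID1B 0.73 ± 0.15, GA2 -0.54 ± 0.12).

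Heat shock genes were higher in ckg, but in replicates 1 and 2 far more than in replicate 3. All 13 measured members had higher signal, with a list mean of 1.03 (log2, SD 0.32), a 2.04-fold higher level; camera, over the 10 members with a value on every array, gave an adjusted p of 1.6e-04. The adjusted p was 0.986 with an estimated correlation, and the fry adjusted p was 0.409. HSP15.7, a small heat shock protein, was higher by 1.62 ± 0.36 and HSP90.1, a cytosolic chaperone, by 0.96 ± 0.24; 3 members passed adjusted over the list alone, 5 were at an unadjusted p under 0.05, and 0 passed over all genes in limma. The 3 over the list alone became 13 without ckg replicate 3 and 0 without any other array or with quantile scaling. List means were -0.56 and -0.68 on the Col-0 arrays and 0.89, 0.82 and -0.39 on the ckg arrays. As many as 2 of the 10 splits of the arrays gave a difference as large (exact permutation p = 0.2).

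**Figure D3:**
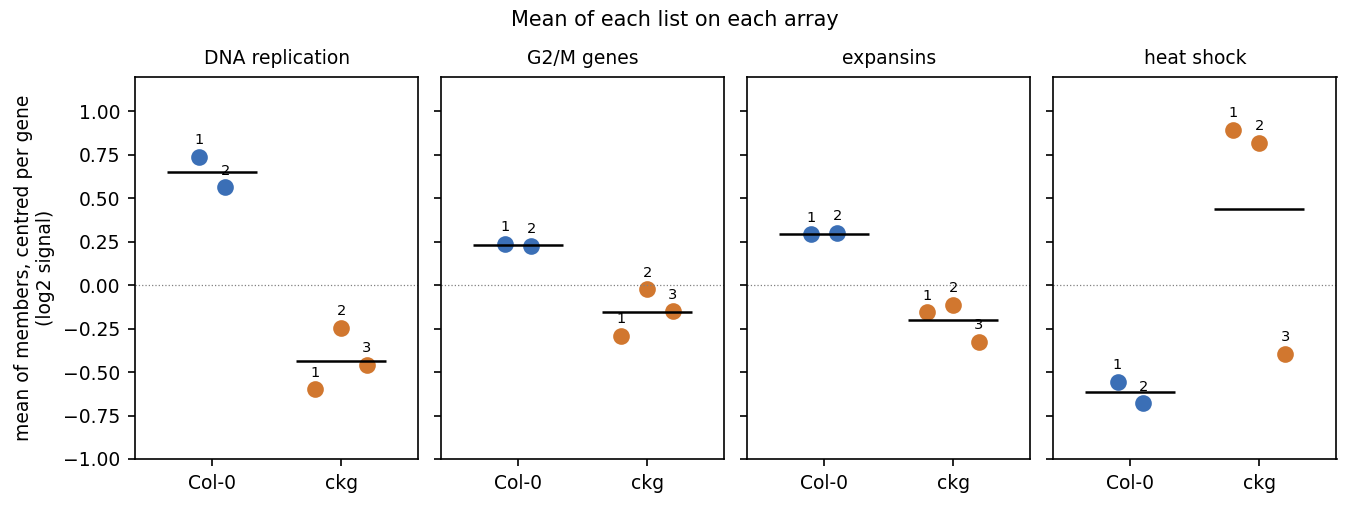
Mean of the measured members of each of 4 lists on each array (log2 signal centred per gene, y axis); points are arrays with their replicate number, and black bars are group means. The DNA replication, G2 and M phase and expansin means of all 3 ckg arrays lie below both Col-0 arrays, while the heat shock mean of ckg replicate 3 (-0.39) lies near the Col-0 arrays (-0.56 and -0.68).

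Among other stress lists, the abscisic acid, cold and drought genes went both ways (mean -0.06, median 0.22 over 20 genes; camera adjusted p = 0.779). COR15B, a cold-induced chloroplast protein, was lower by 3.27 ± 0.44 and RD29B, a marker of abscisic acid response, higher by 1.72 ± 0.24, and 6 members passed over the list alone. Jasmonate and wounding genes had a mean of -0.01, positive under another scaling, and a median of 0.15 over 22 genes (camera adjusted p = 0.675; AOC1 1.16 ± 0.36, JAZ5 0.73 ± 0.26). Without ckg replicate 2 that mean was 0.17 and passed at the preset correlation (camera adjusted p = 0.00544), though not with an estimated one. Salicylic acid defence genes had a mean of 0.01, negative under other scalings (15 genes, camera adjusted p = 0.987; ICS1 -0.51 ± 0.19, with another probe at 0.46; WRKY54 -0.23 ± 0.10). Touch and handling responses had a mean of 0.01, negative under another scaling (10 genes, camera adjusted p = 0.916; CML24 0.18 ± 0.12, RHL41 0.16 ± 0.15).

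Light harvesting and Rubisco small subunit genes had a mean of -0.18 over 22 genes (camera adjusted p = 0.0658). Their mean passed at -0.29 without ckg replicate 3 (camera adjusted p = 1.96e-04), and the list also passed camera with normexp, without the filter, with the filter on all 5 arrays, with the mean of probes, with the replicate block and with unmatched probes tested too. With an estimated correlation the list passed in none of these settings. LHCB2.3, a protein of the photosystem II antenna, was at -1.29 ± 0.11 and passed over the list alone, and LHCA4 was at -0.36 ± 0.13; of 72 other probes of these genes, 18 had the opposite sign. Chlorophyll synthesis genes had a mean of 0.05, negative under other scalings (11 genes, camera adjusted p = 0.985; PORB -0.31 ± 0.10, PORC 0.86 ± 0.14, with another probe of PORC at -0.15). Flavonoid and anthocyanin synthesis genes had a mean of -0.46 over 8 genes (camera adjusted p = 0.763). Per-array means of these 8 were 0.21 and 0.35 in Col-0 and -0.28, 0.05 and -0.32 in ckg. With the same probes, leaving out ckg replicate 3 therefore does not turn their sign. A list mean of 0.63 without that replicate came with the filter and probe choice applied anew, which can change the members. FLS1 (-0.73 ± 0.18) and F3H (-1.25 ± 0.31), enzymes of flavonol synthesis, were among 4 members that passed over the list alone, 3 lower and 1 higher. Of the 8 flavonoid genes 4 were higher and 4 lower in ckg, with a median of -0.07. The circadian clock list had a mean of 0.13 over 25 genes (camera adjusted p = 0.189), with PRR7, a morning-phased repressor, at -1.09 ± 0.17 and GRP8, an RNA-binding clock output, at 0.68 ± 0.12; both passed over the list alone.

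In the nutrient lists, PAP17, an acid phosphatase induced by phosphate starvation, was higher by 1.71 ± 0.16 and PHT1;4 by 0.31 ± 0.11. The phosphate starvation list had a mean of 0.47 over 8 genes (camera adjusted p = 0.129), and 0.56 without ckg replicate 3, where it passed (camera adjusted p = 0.0274); it also passed camera with normexp, with the series table and with the replicate block, though in no setting with an estimated correlation. Sulfur deficiency genes had a mean of 0.13 over 6 genes (camera adjusted p = 0.680; LSU2 0.92 ± 0.18, APR2 0.56 ± 0.17), and iron genes a mean of -0.07 over 9, positive under another scaling (camera adjusted p = 0.944). BTS was at -0.30 ± 0.11 and BHLH101 at -0.26 ± 0.17, both above 0 with normexp. Aliphatic glucosinolate genes had a mean of 0.005, negative under another scaling (12 genes, camera adjusted p = 0.840; MAM1 0.33 ± 0.12, CYP83A1 0.29 ± 0.14). The cytosolic ribosomal protein list held only the 7 genes that the reference table describes as such (mean 0.06, camera adjusted p = 0.916; RPSAb 0.42 ± 0.25, RPL18AA 0.36 ± 0.28).

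Markers of other tissues and cell types did not pass. Shoot apex and leaf primordium markers had a median of -0.00168 and a mean of 0.02, negative under other scalings, over 7 of 16 fixed genes (camera adjusted p = 0.925; GRF3 0.45 ± 0.23, GIF1 0.09 ± 0.12). Root markers had a mean of 0.18 over 6 genes, negative under another scaling (camera adjusted p = 0.526; COBL9 0.29 ± 0.17, CASP2 0.25 ± 0.19). Trichome regulators had a mean of 0.13 over 2 genes, negative under another scaling (camera adjusted p = 0.944; TRY 0.69 ± 0.29, CPC -0.44 ± 0.22). Stomatal lineage genes had a mean of -0.17 over 14 (camera adjusted p = 0.167); SDD1, a protease that limits stomatal density, was at -0.63 ± 0.10 and MUTE, a factor of guard cell formation, at -0.76 ± 0.19. Epidermis genes had a mean of -0.05 over 8 (camera adjusted p = 0.879; PDF1 -0.51 ± 0.16, PDF2 0.35 ± 0.13). Vascular genes had a mean of -0.30 over 11 (camera adjusted p = 0.129; XCP1 -0.66 ± 0.20, MYB46 -0.82 ± 0.27), and -0.41 without ckg replicate 2, where they passed (camera adjusted p = 0.00451). Without the filter on dim probes the vascular, stomatal lineage and cellulose synthase lists also passed camera; none of these calls held with an estimated correlation. Seed storage and lipid mobilisation genes had a mean of 0.27 over 3 genes, negative under another scaling (camera adjusted p = 0.566, MLS 0.57 ± 0.19, ICL 0.21 ± 0.31). Per-array means of these 3 were -0.36 and 0.04 in Col-0 and 0.01, 0.29 and 0.02 in ckg. The list mean ran from -0.58 to 0.42 when 1 array was left out. The filter and probe choice were then applied anew, which can change the members. In all, 4 of 34 lists passed camera with the preset correlation, 0 with an estimated one, 0 in fry in a single direction and 17 in its mixed form. Mean, median and test differed in sign for 10 lists: those of type-A response regulators, xyloglucan enzymes, auxin, gibberellin, ribosomal proteins, chlorophyll, salicylic acid, jasmonate, abscisic acid and the shoot apex.

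Across single genes, LBD26, THI2.2 and AT3G05170 shared the smallest adjusted p (0.0539 in limma), and 0 of 18123 genes passed 0.05. At an unadjusted p under 0.05 there were 3283 genes (1505 higher and 1778 lower in ckg), 18.1% of those tested, against 906 by chance, and 346 of them differed at least 2-fold, with the split the other way (209 higher and 137 lower). The count was 1579 without Col-0 replicate 1 (834 higher, 745 lower) and 1696 without Col-0 replicate 2 (895 higher, 801 lower), so the balance of direction turned when either was left out. Without the filter on dim probes the split at an unadjusted p under 0.05 in limma was near even (1301 higher, 1282 lower). With limma's trend and robust options 4 genes passed, and without ckg replicate 3 there were 3. In 3532 genes every ckg array lay above both Col-0 arrays and in 4121 below, 42.2% of genes together, where chance gives 20%. At a limma adjusted p under 0.10, a threshold chosen after seeing the data, there were 130 genes, 48 higher and 82 lower. That count ran from 0 without ckg replicate 1 or ckg replicate 2, through 1 without Col-0 replicate 2 and 37 without Col-0 replicate 1 (35 higher, 2 lower), to 660 without ckg replicate 3 (352 higher, 308 lower), so the excess of lower genes did not hold. The number past 0.10 was 400 with normexp (178 higher, 222 lower), 4 with quantile scaling (1 higher, 3 lower), 9 with the mean of probes, 39 with the series table, and 0 without the filter or with the replicate block.

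The following genes were named from the 130 after their values were seen. Higher in ckg were CUTA, a protein related to copper tolerance factors (8.59-fold), the myrosinase-binding proteins MBP1 (2.77 ± 0.20, SE) and MBP2 (2.71 ± 0.24), and BEE3 (2.05 ± 0.25), a helix-loop-helix factor of brassinosteroid response. Lower were LBD26 (-2.87 ± 0.14), a LOB-domain factor, the thionin THI2.2 (-2.10 ± 0.12) and the beta-tubulin TUB1 (-1.57 ± 0.17). AT3G05170 was well above background on 0 of 2 Col-0 arrays and 3 of 3 ckg arrays, at least 60.7-fold higher in ckg. Its nearest measured neighbours AT3G05165 (0.18 ± 0.14) and AT3G05180 (-0.07 ± 0.13) lay near 0. In all, 22 genes were well above background on every Col-0 array and no ckg array. Of these 1, AT5G50915, had a bound of at least 4-fold. The reverse was seen for 1 gene, AT3G05170. The counts of 22 and 1 cannot be compared, since a call on every ckg array includes ckg replicate 3. There the lowest signal well above background was -3.83 (scaled log2), against -7.40 to -6.96 on the other arrays.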

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

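The tests in this part of the slide, the shoot apex markers, the spread of heat shock genes, the place on the chromosomes and the unmatched probes were chosen only after the result was seen. Probes that match no gene of the reference table lie outside the comparison of genes. Of 3475 such probes measured in at least 1 group, 4 were well above background on every ckg array and no Col-0 array. The reverse held for 12, and the largest bound was at least 6.94-fold higher in ckg. The counts of 4 and 12 cannot be compared, since a call on every ckg array includes ckg replicate 3, where fewer spots were called. At an unadjusted p under 0.05 in limma there were 639 of them. No gene is named for these probes.

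DNA replication and G2 and M phase genes were lower in ckg, with list means of -1.09 and -0.39, and neither list passed camera with an estimated correlation (adjusted p = 0.625 and 0.986). A bias between arrays that depends on signal strength was argued against: among 10000 random lists matched on mean signal, 0 had a mean as low as the replication list and 3 as low as the G2 and M phase list. A smaller share of shoot apex and leaf primordium tissue in ckg was predicted to lower its markers about as much as the replication genes. The 7 measured of 16 markers showed no such fall, with a median of -0.00168 (SD 0.26, range -0.38 to 0.45). STM, CLV3 and WUS were too dim to test, so less apex tissue in ckg is not excluded. Marker means were 0.03 and -0.05 on the Col-0 arrays and -0.39, 0.19 and 0.23 on ckg replicates 1 to 3. Replicate 1 was also the lowest in the replication genes (-0.60). The hybridisation slide stays open too, since 0 slides held both genotypes, and slide and genotype cannot be told apart for these genes. Lower cell cycle activity through the mutation may underlie the pattern, but this was not tested apart from the slide or the share of apex tissue.

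The higher level of heat shock genes may reflect variation between single samples unrelated to genotype. The list mean ranged over 1.29 among the ckg arrays, 1.22 times the difference of 1.06 between the groups, while the Col-0 arrays ranged over 0.12. An effect of genotype on these genes stays open, since 3 of 3 ckg arrays lay above both Col-0 arrays.

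Genes at an adjusted p under 0.10 could lie in a linked segment of another accession around the mutation or elsewhere. The most crowded window of 50 neighbouring tested genes held 4 of the 130, and 4350 of 10000 shuffles of the genes gave a window as crowded (median 3). Windows on chromosomes 2, 3 and 5 tied at 4. The one on chromosome 5, from AT5G52200 to AT5G52950, lies by its locus tags near AT5G50915. Among the 25 tested genes on either side of AT5G50915, 0 were of the 130, so that stretch held none of the 4 genes of the window. The count leaves a short segment open, as it would hold few tested genes, and also a longer one that reaches the window on chromosome 5. AT3G05170, measured in ckg alone, remains without a tested explanation.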

How the results depend on the processing

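Of the settings here, normexp on median intensities, the threshold of 0.10 and the test of probes with no locus were chosen only after the data were seen. The slide could not be fitted as a block, since each slide held 1 genotype, and was not run; the transcript of AT5G50915 has no value under the filter on all 5 arrays, which removes it. In ckg replicate 3 the raised lowest signal (31.0, against 2.68 to 4.01) limits weakly expressed genes. Where 1 Col-0 array was left out, the other was assumed to vary like the ckg arrays. Replication, G2 and M phase, expansin and heat shock lists kept their direction and, at the preset correlation, their camera call under 16 alternatives each, at list means of -1.18 to -0.79, -0.52 to -0.27, -0.60 to -0.03 and 0.77 to 1.502. Genes past the threshold, 0 in limma with 3283 at an unadjusted p under 0.05, numbered 2 with normexp (1 higher, 1 lower), 1 with scaling by the median (1 lower), 3 with the series table (1 higher, 2 lower), 4 with trend and robust (1 higher, 3 lower) and 130 at an adjusted p under 0.10 (48 higher, 82 lower). Leaving out 1 array gave 0 to 3 genes, 0 to 1 higher and 0 to 2 lower, and 1579 to 4286 at an unadjusted p under 0.05. Without the filter on dim probes 8 lists passed and the median of all differences was 0.12. With an estimated correlation and with fry in a single direction 0 lists passed, with fry's mixed form 17, and leaving out 1 array 4 to 6. With the series table AT5G50915 passed at -3.63 (limma adjusted p = 0.0437; 0.0437 to 0.441 over 15 alternatives). The jasmonate and wounding mean, -0.01, ran from -0.11 to 0.17 over left-out arrays and passed above 0 without ckg replicate 2. For all of these shifts the cause was not tested. Over 30 other lists, 386 of 480 values kept direction and side of the threshold, 78 changed sign without passing and 15 newly passed. Over 170 genes, which include every member of the 4 called lists, 2609 of 2668 values kept both, 49 changed sign and 10 newly passed. None of these lists or genes passed in the main fit, so none could lose a pass. Deviations from the group mean correlated across genes at -0.09 and -0.10 between Col-0 and ckg arrays of the same replicate number. Deviations of 2 Col-0 arrays mirror each other, so these values cannot settle whether replicate numbers pair the arrays. With the replicate block 0 genes and 6 lists passed, the 4 lists above among them. AT5G50915 was then at -6.75, as ckg replicate 3 drops out.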

Other observations

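The test on DNA repair and cohesion genes in this part was chosen only after the result was seen. The test on histone genes was set out beforehand, and both lists were added after the data were seen. Genes of DNA repair, cohesion and histones lay mostly below Col-0 in ckg, few of them past a test. Of 26 measured DNA repair and cohesion genes, none of them in the replication or G2 and M phase lists, 23 had lower signal, and 14 had every ckg array below both Col-0 arrays. RPA70B and RPA70D, large subunits of the single-strand binding protein RPA, were at -1.09 ± 0.13 and -1.08 ± 0.15 (SE), POLA2, a subunit of the priming DNA polymerase alpha, at -1.08 ± 0.14 and LIG1, a DNA ligase, at -0.64 ± 0.15. The end-joining gene KU70 was at 0.40 ± 0.16. Over the list alone 7 genes passed, all lower, 11 were at an unadjusted p under 0.05, and 0 passed over all genes in limma. Of 20 measured histone genes, 15 had lower signal, and 3 passed over the list alone: HTA6 (-0.98 ± 0.15), HTA8 (-0.90 ± 0.15) and HTA11 (-0.76 ± 0.14), while HTA9 was at 0.27 ± 0.12. In 8 histone genes every ckg array lay below both Col-0 arrays, and in 2 above. Their means were 0.31 and 0.01 on the Col-0 arrays and -0.16, -0.14 and -0.02 on the ckg arrays. Col-0 replicate 2 and ckg replicate 3 were thus nearly level.

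A hypothesis, not tested independently by the repair and cohesion genes, is that the lower level in ckg may extend from the replication list to the genes of DNA repair, cohesion and histones. The repair and cohesion genes had a mean of -0.45 (camera adjusted p over both lists = 2.5e-05, and 0.0988 with an estimated correlation); their bound was set after the pattern was seen, so their mean lends the hypothesis no weight. The mean of the histone genes, -0.27, lay between the bounds of -0.3 and -0.1 set for it and decides nothing (camera adjusted p = 0.00460, and 0.196 with an estimated correlation). Slide and genotype cannot be told apart here either.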
